A study of Danio rerio with 8 samples.

How the data were processed

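RNA of whole zebrafish embryos at 28 hours post fertilisation was compared on 8 two-colour Agilent arrays. Each array held RNA of embryos carrying an actb2:KIT-D816V transgene in 1 channel and RNA of wild-type AB embryos in the other. Per the labels, the arrays came from 4 replicate experiments, each hybridised in 2 dye orientations, so KIT-D816V was in Cy3 on 4 arrays and in Cy5 on 4. The labels name the dyes Cy3 and Cy5, while the labelling protocol in them names AlexaFluor dyes of the same 2 colours. Per the labels' protocols, the RNA was amplified before it was labelled. Whether the replicates came from separate clutches is not given in the sources used here, so p-values measure only the spread between these 4 replicates.

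Slides were scanned at 532 and 635 nm and quantified with GenePix Pro 5.0.0.51, per the file headers. The deposited spot intensities are linear foreground and local background medians with no normalization, per the file headers. The percent of saturated pixels of each spot was also deposited, and 10% was the limit above which a spot was counted as saturated. The authors' spot flags were -100 for 55.3 to 66.2% of spots per array and -50 for 3 to 32 spots. A separate table holds the authors' processed log2 ratios. Set against the scanner values, its columns correlated at 0.928 to 0.989 with log2 of background-subtracted red over green. The columns therefore run red over green, though a correlation cannot show the base of their logarithm. Their medians were between -0.16 and 0.055. Among probes spotted once, the table held no value at a flagged spot. The authors' background and normalization steps are not given in the sources used here, so the centring of that table stays unknown.

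From the intensities, background was corrected with normexp (offset 50) over all spots, and ratios were normalized by loess within each array, with control spots at weight 0, in limma 3.58.1 under R 4.3.3. Control spots and spots with flag -50 were left out. Spots with flag -100 had median foreground intensities of 41 to 57 in red and 50 to 82 in green per array. Many were above background, and they were kept. On the replicate 1 array with KIT-D816V in Cy3, 55.3% of spots had this flag. Yet 89.7% of probes there were above background in the KIT-D816V channel. Only 12539 probes were unflagged on all 8 arrays, so many of the probes tested include flagged spots. Repeated spots of a probe were averaged, which gave 43603 probes. A probe was kept when its foreground exceeded the background median by 2 background SD on at least 4 of the 8 arrays in the KIT-D816V channel, or on at least 4 in the wild-type channel. This kept 32365 probes and left out 11238. Depth does not apply to arrays, and their number limits the precision.

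Every ratio was turned to KIT-D816V over wild type. The series' design text gives 4 replicate experiments with a dye swap in each. The 2 arrays with a shared replicate number were therefore taken to hold the same pair of RNA samples and were averaged into 1 replicate. The pairing was checked by correlation across probes. The 2 arrays of a number correlated at 0.749, 0.880, 0.531 and 0.771, each above the best correlation of either array with another number, which was 0.28 or less. The 4 averages were fitted with an intercept alone (lmFit, eBayes), p-values were adjusted by Benjamini-Hochberg over all kept probes, and the threshold was an adjusted p of 0.05. Intervals are 95% intervals from the same moderated fit.

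The fit was tested on simulated data of the 32365 probes, with 50 probes changed at each of 4 sizes. It recovered 14 at a log2 size of 1, 39 at 2, 48 at 3 and 46 at 4, and it also called 16 of 32165 unchanged probes. With replicate 4 simulated as exchanged and then turned, it recovered 12, 41, 48 and 46 probes at these sizes and called 20 unchanged ones. Unchanged probes made up 9.82 and 11.98% of the simulated calls, above the nominal 5%. The changed probes were drawn only from the brighter kept probes, and their sizes were set on a scale that already held the offset. The recovery therefore does not describe dim probes. The simulated replicates were independent and shared 1 spread per probe. The SD of the real log2 ratios over probes was 0.31 in replicate 3 and 0.606 in replicate 2. Real replicates correlated at -0.34 to 0.19 across probes. The adjusted threshold also depends on how many probes were changed, so the recovery does not carry over to the real fits.

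The array files identify probes only by the manufacturer's ID. None of these IDs was found in the gene tables used here (0 matches), so no probe was given a gene name. The 40 gene lists and the named genes fixed before the data were examined, among them kita, kitb, mitfa and gata1a, were therefore not analysed here. The rule for single probes became, after the data were examined, the probe with the smallest p in each direction, as labelled and with replicate 4 turned. Replicate 4 ran against the others, so each comparison is also given with its ratios turned to the opposite sign and without it, both chosen after the data were examined, although leaving out each replicate had been planned. Alternatives fixed before the data were examined were other background corrections, median centring, Aquantile, other filters, the authors' values, 8 arrays with or without the replicate block, each dye orientation alone, a trended robust prior, slide as a block and leaving out each replicate. Where a probe was above background on no array of a side, its fold is a bound, computed per channel after loess and Aquantile from the higher of its own signal and the lowest signal above background on that array.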

Results

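The series compared transcript levels in whole zebrafish embryos with and without KIT-D816V, an activated form of the receptor tyrosine kinase KIT, placed under the promoter of the widely expressed beta-actin gene actb2. Substitutions of this kind are found in human systemic mastocytosis, a disease of mast cell excess. All embryos were of the AB strain and were taken at 28 hours post fertilisation. The 8 arrays formed 4 replicates, each a dye swap of 2 arrays. Signals were low, with median foreground intensities of 54 to 88 in red and 79 to 160 in green, over median backgrounds of 32 to 41 and 33 to 46. Between 52.7 and 89.7% of probes per array were above background in the KIT-D816V channel, and between 56.0 and 80.6% in the wild-type channel. At most 18 spots per array were saturated in red and at most 82 in green.

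Within a dye swap, the arrays gave similar KIT-D816V over wild-type ratios. Across 32365 probes, which are not independent replicates, the correlation was 0.749 in replicate 1, 0.880 in replicate 2, 0.531 in replicate 3 and 0.771 in replicate 4. The mean of 0.733 was 0.372 when median centring replaced loess. Between replicates the ratios had little in common. The correlation was 0.19 for replicates 1 and 3, 0.13 for replicates 2 and 3, and -0.16 for replicates 1 and 2, which shared a slide. Replicate 4 as labelled correlated at -0.015 with replicate 1, at -0.33 with replicate 2 and at -0.34 with replicate 3. Among arrays of the same dye orientation, the lowest value was -0.301, for replicates 3 and 4 with KIT-D816V in Cy5. The direction of the ratios is therefore not settled between replicate 4 and the others, and each comparison is given as labelled, with replicate 4 turned and without it. The mean correlation between replicates was -0.087 as labelled and 0.141 with replicate 4 turned.

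**Figure D1:**
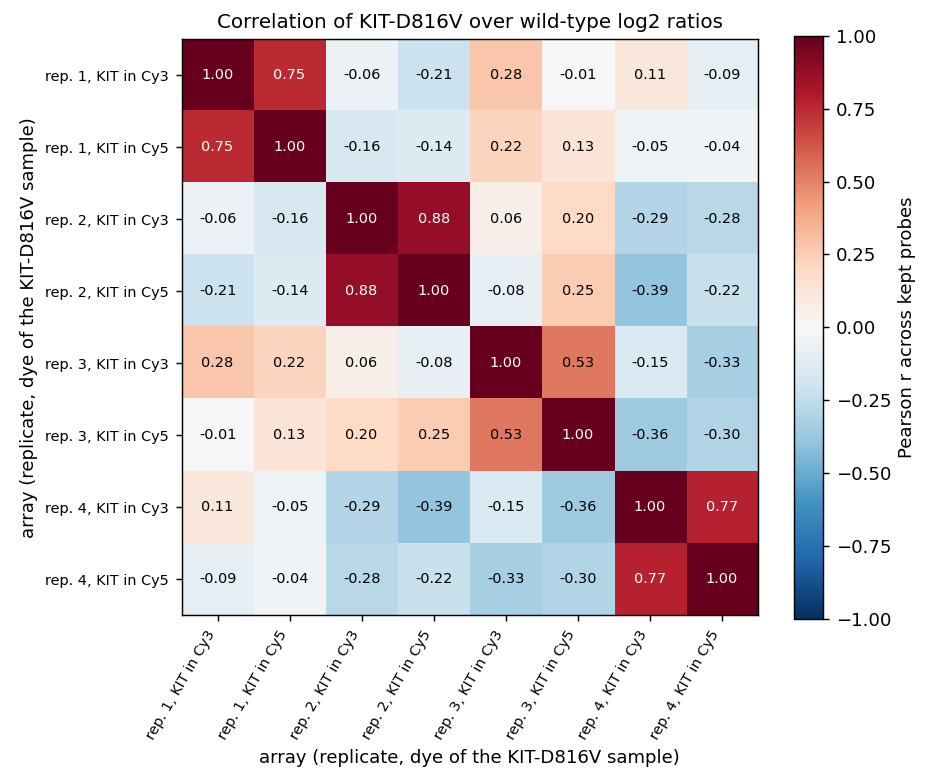
Pearson correlation across 32365 probes of the log2 ratios (KIT-D816V over wild type) between the 8 arrays, with arrays named on both axes by replicate and by the dye of the KIT-D816V sample. The 4 dye swaps stand out at 0.53 to 0.88, and replicate 4 is below 0 against replicates 2 and 3 on every pair of arrays.

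As labelled, no probe passed the test for a difference between KIT-D816V and wild-type embryos. The limma fit on 4 replicates called 0 of 32365 probes at the adjusted threshold, and 541 probes had an unadjusted p under 0.05, which is 1.67% of those tested. Ratios had the same sign in all 4 replicates for 7.12% of probes, where independent signs give 12.5%. No probe was beyond 2-fold the same way in all 4 replicates. The 95% interval of the mean ratio lay within 2-fold in either direction for 29282 probes, or 90.5%. With replicate 4 turned these figures were 29150 probes and 90.1%, and the sign was shared by all 4 replicates for 15.2% of probes. Without replicate 4, the interval lay within 2-fold for 27172 probes, or 84.0%. The sign was then shared by the 3 replicates for 22.3% of probes, where independent signs give 25%. All these ratios hold the normexp offset, which makes the ratios of dim probes smaller. With replicate 4 turned, 45 probes were beyond 2-fold in all 4 replicates on this scale, and 137 with the scanner's local background subtracted. The shares within 2-fold therefore hold for this scale and do not bound the change of dim transcripts. Of the 10 probes with the smallest p as labelled, 8 were higher and 2 were lower in KIT-D816V embryos by the mean ratio, with log2 sizes between 0.49 and 1.07, and none passed. The count was also 0 under every alternative fixed before the data were examined.

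The probe with the smallest p among those with a higher ratio was A_15_P754726, at a log2 ratio of 0.90 ± 0.18 (SD, n = 4). Its limma p was 0.000354 and its adjusted p was 1, although the ratio was above 0 in all 4 replicates. The probe with the smallest p among those with a lower ratio was A_15_P627141, at -1.07 ± 0.36 (SD, n = 4), below 0 in all 4 replicates, with a limma p of 0.00121 and an adjusted p of 1. With replicate 4 turned, their log2 ratios became 0.39 and -0.66, at limma adjusted p values of 0.864 and 0.792. Without replicate 4, they were 0.86 ± 0.20 and -1.15 ± 0.39 (SD, n = 3). Neither ratio reached the threshold in any of these fits, and neither probe has a gene name here.

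Without replicate 4, the limma fit on 3 replicates also called 0 probes, and 1374 had an unadjusted p under 0.05. In these 3 replicates, 60 probes were beyond 2-fold the same way, 21 of them higher and 39 lower in KIT-D816V embryos. In replicate 4 as labelled, 57 of the 60 went the opposite way, and 45 of these did so by more than 2-fold. Over the 60 probes, the median absolute log2 ratio was 1.66 in replicates 1 to 3, and the median in replicate 4, read in the direction of the others, was -1.44. Choosing probes in this way on the other 3 replicates gave 0 probes when replicate 1 was left out, 0 for replicate 2 and 3 for replicate 3.

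**Figure D2:**
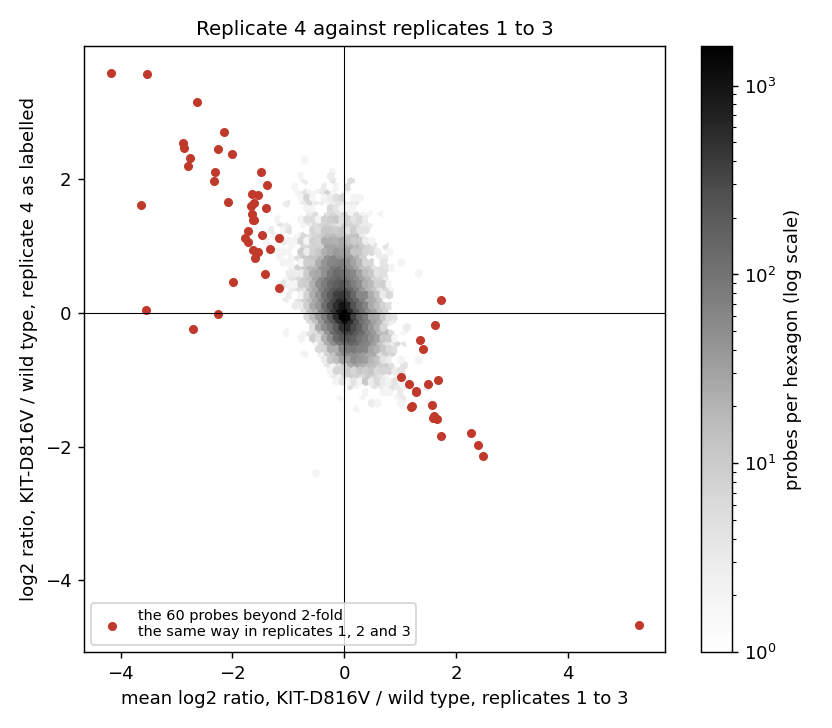
Log2 ratio (KIT-D816V over wild type) in replicate 4 as labelled on the vertical axis against the mean of replicates 1 to 3 on the horizontal axis, with all probes as grey hexagons shaded by their number on a log scale and the 60 probes beyond 2-fold the same way in replicates 1 to 3 in red. Of the red points, 57 have opposite signs on the 2 axes.

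With replicate 4 turned, 5 of 32365 probes passed the limma threshold, 2 of them higher and 3 lower in KIT-D816V embryos, and 2340 had an unadjusted p under 0.05. Replicate 4 was turned because its ratios had been seen to oppose the others. The p-values and counts with it turned do not allow for that choice. In this reading, 45 probes were beyond 2-fold the same way in all 4 replicates, 16 higher and 29 lower. The other sign patterns of the 4 replicates gave 0 or 1 such probe. The count at an unadjusted limma p under 0.05 did not single out replicate 4. Turning replicates 2 and 3 gave more, 3233 probes, and turning replicate 2 alone gave 2130. The remaining patterns gave between 541 and 1749. The 45 became 137 with the scanner's local background subtracted, 44 higher and 93 lower, and 26 among probes above background on all 8 arrays in both channels. Over the 3 replicates that remained, they became 74 without replicate 1 and 79 without replicate 3. In the authors' processed values, 37 of the 12539 probes with values in all replicates did so with replicate 4 turned, 0 did as labelled, and at most 1 did under any other pattern. Those values come from the same arrays and are not independent of the choice. Under median centring in place of loess, 1 higher and 7 lower probes passed, and 8 higher and 39 lower probes were beyond 2-fold. With no background subtraction, 3 higher and 9 lower probes passed. The scanner's local subtraction passed 63 higher and 141 lower probes. The 5 calls were lost when any replicate was left out, which brought the count to 0 each time, and the count was 1 with slide as a block. In simulated data of this kind, 11.98% of calls were unchanged probes. That share depends on how many probes were changed in the simulation, so it does not carry over to the 5 calls.

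Some probes were above background almost only in wild-type embryos in this reading. With the sides of replicate 4 exchanged, 19 probes were above background on at least 7 of the 8 arrays in wild type and on at most 1 in KIT-D816V embryos, and 1 probe was so the other way. As labelled, the counts were 0 and 0. Exchanging the sides of any other replicate gave at most 1 such probe.

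The probe with the smallest p among those higher with replicate 4 turned was A_15_P410615, at a log2 ratio of 5.11 ± 0.46 (SD, n = 4), or 34.6-fold, with a limma adjusted p of 0.0212. The size depended on the background step, and the log2 ratio was 6.19 with the scanner's local background subtracted. In this reading it was above background on all 8 arrays in KIT-D816V and on 7 of 8 in wild-type embryos. As labelled, its ratios were 4.78, 5.45 and 5.57 in replicates 1 to 3 and -4.66 in replicate 4, a mean of 2.78 ± 4.97 (SD, n = 4) at a limma adjusted p of 1. Its median background-subtracted intensity was 3702 in KIT-D816V and 59 in wild-type embryos over replicates 1 to 3, against 75.5 and 2414.5 in replicate 4 as labelled. The probe with the smallest p among those lower was A_15_P138896, at -2.80 ± 0.20 (SD, n = 4) with replicate 4 turned and a limma adjusted p of 0.0212. As labelled, its mean was -1.53 ± 2.71 (SD, n = 4), with 2.53 in replicate 4 against -2.75 or below in each of replicates 1 to 3, and its limma adjusted p was 1. In replicates 1 to 3, A_15_P138896 was not above background on any KIT-D816V array and was above it on all 6 wild-type arrays, and in replicate 4 as labelled the 2 sides changed places. With replicate 4 turned, it was at least 6.77-fold lower in KIT-D816V embryos. Its log2 ratios and their SD are set by the floor of the undetected side, and the ratio was -5.32 with local background subtracted. Without replicate 4, the log2 ratios of the pair were 5.27 ± 0.42 and -2.88 ± 0.13 (SD, n = 3), each at a limma adjusted p of 0.151. Both were singled out, and replicate 4 was turned, after the values were seen. The limma adjusted p of 0.0212 does not allow for these choices. Neither probe has a gene name here. When each replicate was left out in turn, the log2 ratio of A_15_P410615 was between 4.96 and 5.27, and neither probe passed the threshold with 3 replicates. They also missed it with slide as a block, and on the arrays with KIT-D816V in Cy5 alone.

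**Figure D3:**
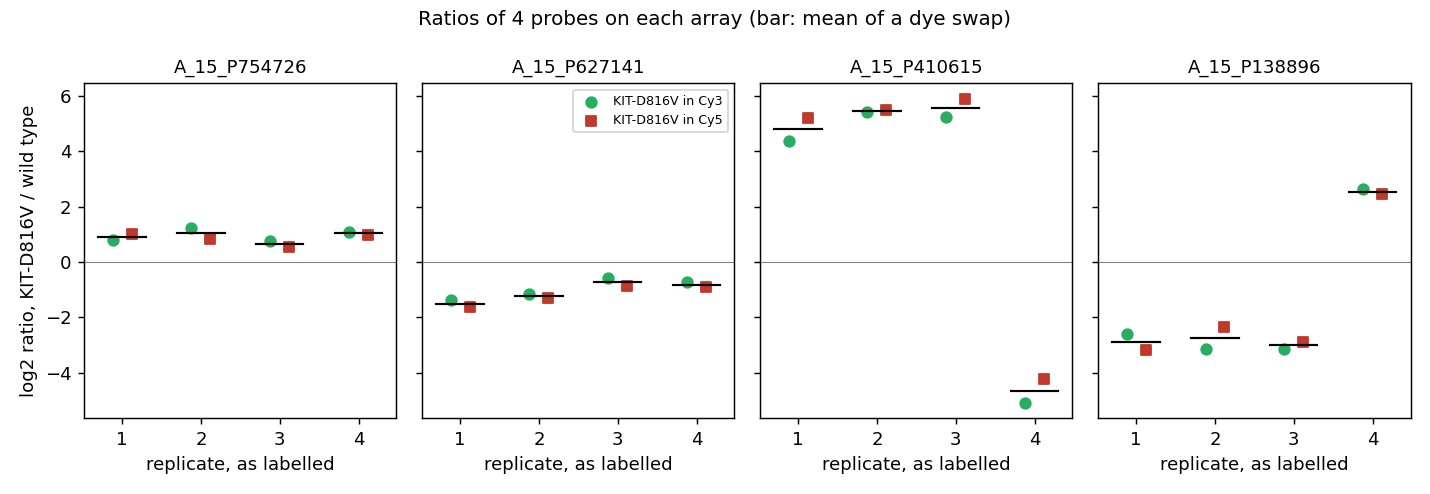
Log2 ratio (KIT-D816V over wild type) of 4 probes on each of the 8 arrays by replicate as labelled, with circles for KIT-D816V in Cy3, squares for KIT-D816V in Cy5 and a bar for the mean of each dye swap. A_15_P754726 and A_15_P627141 keep their sign in all 4 replicates, while A_15_P410615 and A_15_P138896 change sign in replicate 4, to -4.66 and 2.53.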

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

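All tests in this part were chosen after the results were seen. Replicate 4 stood far from the other 3 replicates for 2 of the probes described, at a log2 ratio of -4.66 for A_15_P410615 and of 2.53 for A_15_P138896. Both had been picked with replicate 4 turned, so these 2 values are not independent of that choice. Among the arrays with KIT-D816V in Cy3, replicate 2 had a median green foreground intensity of 79, far below the others, the lowest of which was 137. These came from 19 sets of 4 values, and chance alone marks about 1 set in 20.

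The pattern that replicate 4 opposes replicates 1 to 3 was weighed against 3 explanations. An exchange of the red and green columns of replicate 4 would also have turned its dye effects, but these correlated with those of replicates 1 to 3 at 0.373 or more across probes, which argues against it. An exchange of the labels or of the 2 RNA samples of replicate 4 is a candidate explanation: of the probes chosen on replicates 1 to 3 alone, 95% went the opposite way in replicate 4, where an unrelated replicate would give about as many either way. An opposite difference between the embryos of replicate 4 stays open, since the median ratio of its log2 values to theirs was -0.856 and no gene names were used that could tell the 2 genotypes apart by the transgene or its targets. The same values would arise if replicates 1 to 3 were the exchanged ones, so which side carries KIT-D816V is not settled by these data.

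The ratios also differed between replicates 1, 2 and 3. Replicates 1 and 2 shared a slide, yet they correlated at -0.159, below the 0.192 of replicates 1 and 3. A difference between slides cannot account for how replicates 1 and 2 differed. Replicate 3 was alone on its slide, as was replicate 4, so slide cannot be told apart from the replicate there. A slide effect on red over green would also cancel in averages of both dye orientations, so these correlations could not show it. No biological explanation was tested.

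The 4 replicates allow 8 splits into signs, so the share is never under 0.125 and is too large to judge chance. As labelled, the count of probes past the threshold was 0, the highest other split gave 5, and all 8 splits, the real one included, gave at least as many. Any split matches a count of 0, so this could not have come out otherwise. With replicate 4 turned the count was 5, the highest other split gave 0, and 1 split, the turned one itself, gave as many. That split was chosen after the ratios were seen, so its count is no test of chance.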

How the results depend on the processing

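The alternatives applied to the turned replicate 4, the missing treatment of spots with flag -100, the lower size limit and the fit within slide 1 were chosen after the data were seen. As labelled, the count of probes past the threshold was 0 under all 19 alternatives that keep the labels, with 123 to 2243 probes at an unadjusted p under 0.05, and it became 5 only with replicate 4 turned. That includes 8 arrays with the replicate block, without it, and replicates 1 and 2 of slide 1 alone. With replicate 4 turned, the count of 5 became 134 with the replicate block, 662 with no block, 12 with no background subtraction, 204 with local subtraction, 8 with median centring, 32 with the authors' values, 32 without spots of flag -100, 108 with a trended robust prior, 1 with KIT-D816V in Cy5 alone, 1 with slide as a block and 0 without any replicate. The fit with no block treats the arrays of a dye swap as independent; the cause of the other changes was not tested. The 45 probes beyond 2-fold in all replicates became 137 with local subtraction, 26 among probes above background on all 8 arrays, 187 at a log2 limit of 0.5, and 56 to 79 when a replicate was left out, which leaves fewer replicates to meet the limit. The mean dye-swap correlation fell to 0.372 with median centring, and the mean between replicates was 0.141 with replicate 4 turned. Aquantile acts on average intensities alone and moved no ratio, so that alternative could not have given another count. The log2 ratios of the 4 probes described kept their sign throughout, but local subtraction moved A_15_P410615 from 5.11 to 6.19 and A_15_P138896 from -2.80 to -5.32. These 2 lost the threshold in 6 of 17 alternatives each, with adjusted p values up to 0.366. Gene lists, camera, fry and the mean of a gene's probes were not run. Low signal limits what can be seen: 11238 dim probes were left out of the counts reported, and with no filter the count was 0 as labelled and 6 with replicate 4 turned.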

Other observations

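The tests in this part were chosen after the data were seen. Replicate 2 had the most probes beyond 2-fold on both of its arrays, 1286 higher and 1150 lower in KIT-D816V embryos, and replicate 3 the fewest, 94 higher and 213 lower. Replicate 1 had 435 and 186, and replicate 4 as labelled 640 and 106. The 2 arrays of a dye swap were beyond 2-fold in opposite directions for 1 to 17 probes.

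Probes beyond 2-fold in replicate 1 tended to be so in replicate 2 in either direction. They shared 135 probes that went the same way, where independent lists give 23.9, and 136 that went opposite ways, where independent lists give 22.8. Replicates 1 and 3 shared 69 probes the same way and 6 opposite, against 2.49 and 3.40. Replicates 2 and 4 as labelled shared 47 the same way and 273 opposite, against 29.2 and 26.95. Replicates 3 and 4 shared 0 the same way and 76 opposite, against 2.56 and 4.52. Replicates 1 and 4 as labelled shared 19 the same way and 82 opposite, against 9.21 and 5.10, so both were above independence. Replicates 2 and 3 shared 95 the same way and 12 opposite, against 11.3 and 11.8.

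The dye effect, the part of a ratio that did not turn with the samples, passed the limma threshold for 891 of 32365 probes, 375 brighter in Cy5 and 516 brighter in Cy3, and reached a log2 size of 1.12.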
